A study of Homo sapiens with 38 samples.

How the data were processed

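The data are small RNA sequencing libraries of the acute myeloid leukaemia lines KG1a and HL60, of their lEV and of their sEV, each as total RNA and as rPAL-enriched RNA. Cells were grown with 10% serum and vesicles were collected from cells kept without serum for 2 days, per the labels, so vesicle and cell RNA differ in culture as well as in source. The deposited table holds raw read counts per feature, which the authors made by aligning reads with Bowtie2 to GRCh38 (hg38) per the submitters' processing notes. Their versions, the counting program, the treatment of reads with several hits and the annotation release are not stated. The values were whole numbers and were used as counts. All 38 columns matched a labelled sample, and no batch or date label was given.

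The table has 90127 features, 86401 with Ensembl and 3726 with RNAcentral identifiers, of which 20365 had no count in any library. GENCODE release 29 gave a symbol and GRCh38 coordinates to 57355. RNAcentral entries have no gene name in the references at hand, so they are described by class only. Features without a symbol held 85.6% of counts. RNAcentral entries held 97.1% of miRNA, 98.95% of 7SL, 96.3% of snoRNA and 70.9% of snRNA counts, so a named Ensembl gene of these classes holds only a part of its RNA. Features whose log2 counts differ by at most 0.2 in every library are taken to share reads, 47 of the 1015 features with at least 5000 counts, in 15 groups. Of each group only the feature with a symbol that is most abundant in the libraries compared is named. This rule misses features that share reads at a constant ratio. Of protein-coding counts 30.8% lay in genes that hold a small RNA gene on the same strand, so a named mRNA may stand for that small RNA.

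Of the comparisons, 18 were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, quasi-likelihood tests with robust dispersion and Benjamini-Hochberg adjustment within each comparison, called at an adjusted p under 0.05. Only the groups compared entered a fit. Differences in enrichment were interaction contrasts over 4 groups. Fold changes are after TMM scaling and CPM values are per library total, so their ratios can differ. Folds against a group with no count use a floor of 3 counts over the group, and where it moves a fitted class median, the median with these features at the floor is given too. For differences in enrichment, the median of the features with a count in all 4 groups is given where it differs. Class shares are percentages of each library total, computed in Python 3.11.15 with pandas 2.3.3 and tested by a permutation of the RNA kind within line and source. Sets of at least 5 features were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over all classes and comparisons, and also with an estimated correlation and with fry. Camera compares a set with the other features, while fry tests whether a set's features move on balance one way and does not compare them with others. Of 304 class tests 210 were called by camera, 157 by fry and 4 with an estimated correlation, which are the lncRNA falls in KG1a and HL60 lEV against cells, the protein-coding rise in KG1a sEV against cells and the lncRNA difference in HL60 lEV enrichment.

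The comparisons and their tests, RNA classes, 12 gene lists, alternatives and the rule for named genes were chosen before the data were examined. The splits of the libraries, against which the counts of called features were also set, were chosen after. Named genes are the 6 largest and 6 smallest log2 fold changes with an adjusted p under 0.05, a mean of at least 50 CPM and no overlap between groups (4 and 4 by adjusted p and mean for interactions), with a symbol, of which the text gives a part, and a fixed panel that includes RNY1, RNY3, RNY4, RNU4-2 and RN7SL1. In 3 against 3 libraries, 10% of random orders show no overlap. Genes from the lists (CD34, MPO, NEAT1, MIR29A, RPL13A, KCNQ1OT1), the mitochondrial mRNA MT-CYB and PCNA, LINC01766 and the rRNA entries were named after their values were seen. The lists are let-7 genes, myeloid miRNA, ribosomal protein mRNAs, histone mRNAs, nuclear lncRNAs, neutrophil granule mRNAs, stem and primitive cell mRNAs, C/D snoRNA genes and H/ACA snoRNA genes. No member of the lists of MIR17-92 clusters, of miRNA of other tissues or serum, or of erythroid and plasma mRNAs was tested in any comparison (0 tested), since no feature with a listed symbol passed the count filter. The lists match by symbol, and RNAcentral entries without a symbol held 97.1% of miRNA counts. The lack of tests therefore does not show that the listed miRNAs were scarce.

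Replicate numbers might pair libraries, so the correlation of deviations from the group means was computed for libraries of the same number. Only in KG1a sEV against lEV total RNA did every pair exceed 0.1 (0.466, 0.128 and 0.297), and there a fit with the replicate as a block is given beside the unblocked one. The alternatives were DESeq2 1.42.0, library totals without TMM, RLE scaling, no filter, a filter of 10 counts in every library of a group, a replicate block, all 12 groups in one fit, and leaving out each library. Alternatives added after seeing the data were collapsing near-identical features, class shares in cells only, in vesicles only, without rRNA or without 3 libraries that stood apart, and naming the value without such a library.

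The precision is set by 2380745 to 15532758 counts per library, at which 3 counts correspond to 0.193 to 1.26 CPM. These floors cover counting error only, since reads are not independent molecules. The workflow was tested on simulated data, in which 200 features were changed. At an 8-fold change edgeR called 85.4% of changed features in the HL60 cell enrichment and 47.8% in that of KG1a cells, but 0% in the enrichment of vesicles of either line (14% to 30% with DESeq2), so low counts there do not show that features were unchanged. DESeq2 also called 17 to 28 unchanged features in each vesicle enrichment, against 0 or 1 by edgeR. Its larger counts may therefore hold false calls. A lowered class was found in 20 of 20 simulated tables by the share test. Replicates correlated between 0.621 and 0.986 in total RNA. In rPAL libraries of vesicles the correlations were -0.124 to 0.033 in HL60 sEV, 0.206 to 0.239 in HL60 lEV, 0.178 to 0.602 in KG1a sEV and 0.446 to 0.768 in KG1a lEV. In rPAL libraries of cells they were 0.728 to 0.804 in KG1a and 0.858 to 0.882 in HL60. Single unnamed RNAcentral entries, tRNA isodecoders and the comparison of rPAL RNA between sources without its total RNA were left out. Exceptions among the entries were 2 rRNA entries and the RNase P RNA class, which is 1 entry. No library from a pull-down without oxidation is among the samples, so the background of the pull-down was not measured. The result of 1 feature is not reported here.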

Results

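Small RNA was sequenced from 2 human acute myeloid leukaemia lines, KG1a and HL60, and from the large and small extracellular vesicles (lEV and sEV) that they released. Each source was sequenced as total small RNA and after rPAL, in which the sialic acid of glycans is oxidised with periodate and ligated to biotin, so that RNA carrying sialylated glycans (sialoglycoRNA) is pulled down. The 38 libraries form 12 groups, with n = 4 in the KG1a cell groups and n = 3 elsewhere. Total libraries held 5498168 to 14892937 counts and rPAL libraries 2380745 to 15532758, and 18686 to 38503 features had a count in a total library against 7404 to 26722 in an rPAL library. Errors are the SD between libraries for shares and library-scaled read counts (CPM), and the SE of the edgeR fit for log2 fold changes after TMM scaling. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples. Of all counts, 73.1% lay on RNAcentral entries without a gene name, which are described by RNA class only.

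The first question was which RNA classes the rPAL pull-down holds relative to the total RNA of the same source. Precursor miRNA entries fell by 17.3 percentage points between total and rPAL libraries, on average over the 6 sources. They fell from 46.2% ± 1.38 to 10.2% ± 8.69 of counts in KG1a cells and from 20.7% ± 3.05 to 0.827% ± 0.162 in HL60 cells. The smallest fall was in HL60 lEV, from 4.88% ± 2.99 to 0.584% ± 0.141. The KG1a cell rPAL libraries lay apart, at 4.83% and 0.877% in replicates 1 and 4 but 16.04% and 18.96% in replicates 2 and 3. Entries typed only as ncRNA (unspecified ncRNA) fell by 5.49 points, mature miRNA entries by 3.07 points and snoRNA by 1.17 points, and all of these were lower in rPAL in all 6 sources. Precursor and unspecified ncRNA shares moved in parallel in total RNA, at 46.2% and 14.9% in KG1a cells and 4.88% and 1.61% in HL60 lEV. They did so less in rPAL RNA (0.633% and 0.427% in HL60 sEV). Whether the miRNA, precursor and unspecified entries count the same reads was not tested, so their falls are not shown to be independent. RNase P RNA rose in all 6 sources, from 0.0045% ± 0.0018 to 0.325% ± 0.0663 in KG1a cells, 72.1-fold, and 67.0-fold in HL60 cells. Its rise was 20.7-fold in KG1a lEV, 28.8-fold in HL60 lEV, 7.90-fold in KG1a sEV and 10.5-fold in HL60 sEV. Protein-coding features rose by 5.39 points and were higher in rPAL in all 6 sources. Much of this came from HL60 sEV rPAL replicate 2, where PCNA made 40.1% of counts. The rise was 2.97 points without replicate 2 of every group, total and rPAL, and 2.79 points without the 3 libraries that stood apart, of which this library is 1. Ribosomal RNA rose by 19.9 points on average over the 6 sources and was higher in rPAL in 5 of them, as from 5.83% ± 0.969 to 54.8% ± 11.5 in HL60 lEV, but its share in HL60 cells was 13.7% ± 0.974 in total and 6.453% ± 1.2004 in rPAL RNA. The median rRNA feature nevertheless fell in all 6 sources after TMM scaling, with log2 fold changes between -1.13 in KG1a cells and -3.79 in HL60 sEV. A permutation test within sources (100000 resamples, two-sided, Benjamini-Hochberg over 22 classes) called 16 classes, with adjusted p = 3.7e-05 for precursor miRNA, unspecified ncRNA, miRNA, snoRNA, scaRNA and RNase P RNA, 0.00011 for protein-coding features and 0.00018 for rRNA. Within 1 source of 3 against 3 libraries the smallest exact p is 0.1.

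Transfer RNA had no common direction, with a mean difference of 6.02 points and an adjusted permutation p of 0.399. With rRNA left out of the library totals, an alternative added after the data were seen, the mean difference was 15.6 points (adjusted p = 0.037). KG1a sEV was then at 25.3% ± 12.4 in total and 36.3% ± 15.7 in rPAL RNA. With rRNA kept in the totals, the tRNA share was 20.2% ± 0.508 in total and 67.0% ± 6.31 in rPAL RNA of HL60 cells, and 9.99% ± 2.14 and 57.0% ± 20.8 in KG1a cells (exact permutation p = 0.0286, the smallest that n = 4 allows). In these cells rPAL replicates 1 and 4 were at 72.9% and 77.02% and replicates 2 and 3 at 38.7% and 39.6%. In HL60 vesicles the order was the opposite, with 57.3% ± 6.06 in total and 18.5% ± 4.46 in rPAL RNA of lEV, and 37.4% ± 5.10 against 9.48% ± 2.68 in sEV. KG1a lEV (37.2% ± 6.73 in total, 49.6% ± 30.9 in rPAL) and KG1a sEV (17.05% ± 10.6 and 13.5% ± 5.21) differed by less than the spread between libraries. Without rPAL replicate 3, at 16.9%, the share in KG1a lEV was 28.7 points higher in rPAL than in total RNA. The rRNA rise in HL60 vesicles lay largely in 2 unnamed RNAcentral rRNA entries, picked out after the values were seen. These entries made 0.956% ± 0.262 of total and 42.9% ± 9.83 of rPAL counts in HL60 lEV, and 4.25% ± 1.78 and 41.1% ± 9.93 in HL60 sEV. In KG1a lEV they made 3.21% ± 0.446 of total and 22.6% ± 24.3 of rPAL counts and neither was called (adjusted p = 0.063 and 0.269). In KG1a sEV 1 of them was called (0.0318 and 0.0716). All other rRNA features together made 16.4% ± 6.69 of total and 9.82% ± 3.75 of rPAL counts in HL60 sEV, but 4.87% ± 0.732 and 11.96% ± 3.70 in HL60 lEV. In KG1a they made 15.98% ± 3.95 and 11.5% ± 7.41 in lEV, and 29.1% ± 9.69 and 30.4% ± 18.3 in sEV.

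**Figure D1:**
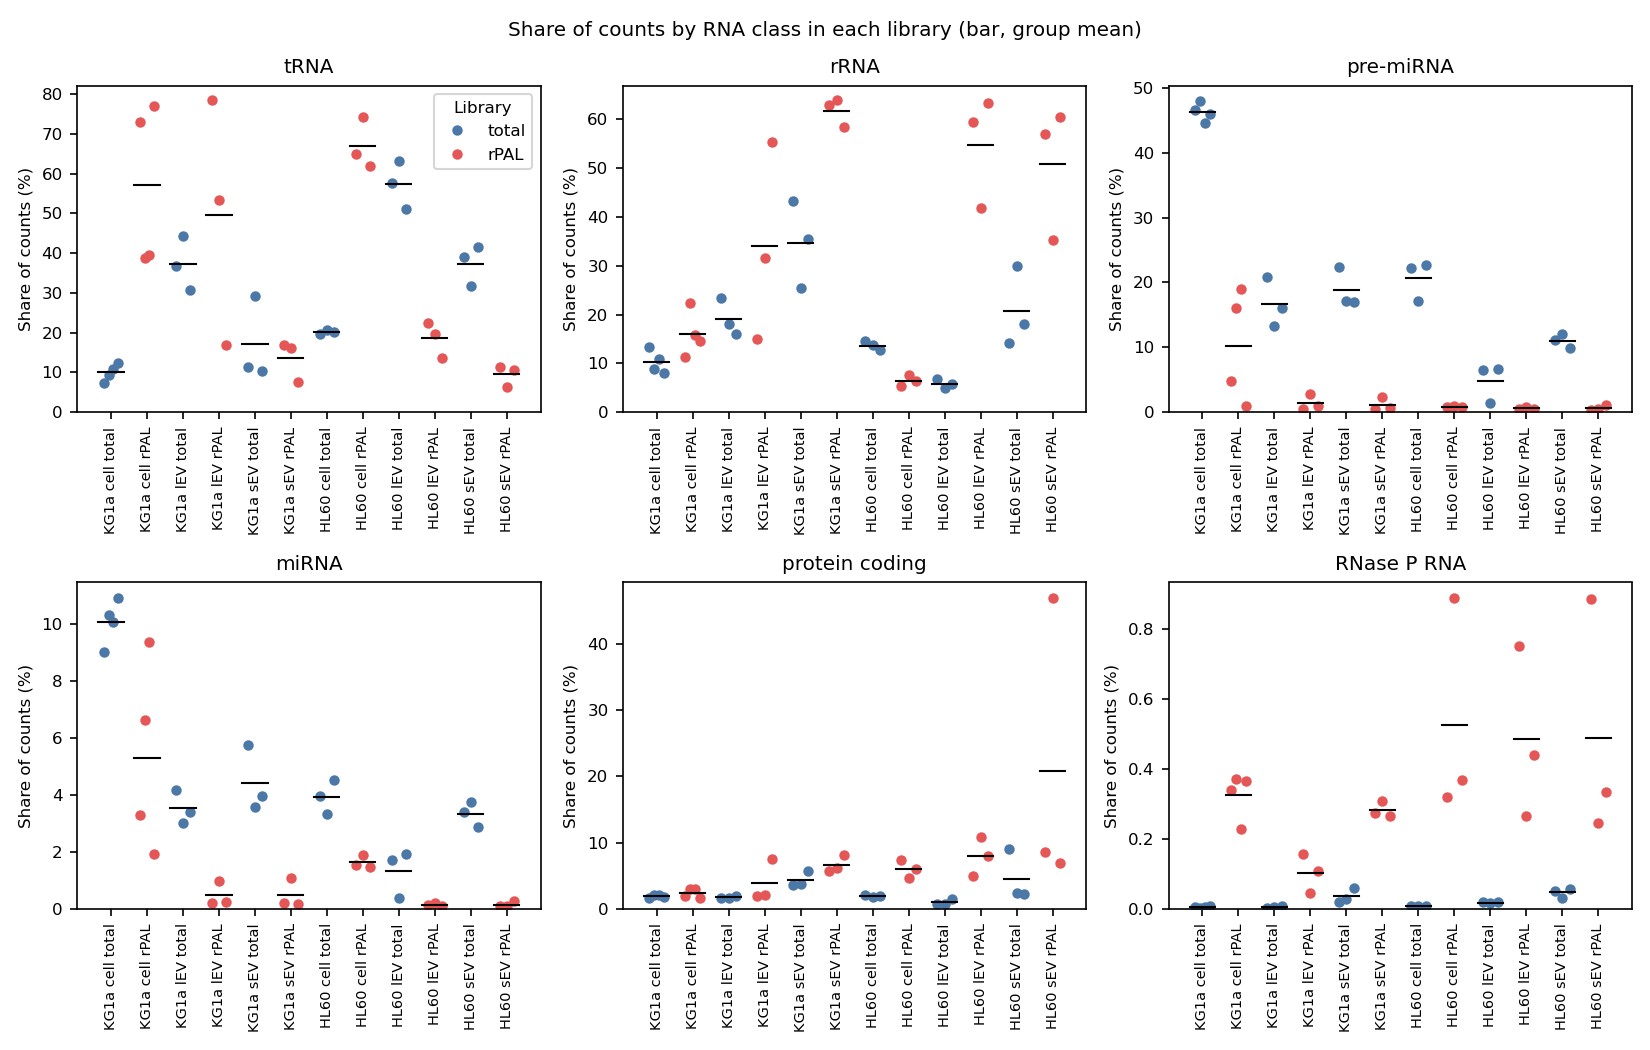
Share of counts (%, y axis) of 6 RNA classes in total and rPAL libraries of cells, lEV and sEV of both lines, with 1 point per library and a bar at the group mean. Precursor miRNA made 20.7% of total and 0.827% of rPAL counts in HL60 cells, while tRNA was 67.0% in the rPAL RNA of these cells and 18.5% in that of their lEV.

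Which features make up the pull-down from KG1a cells was asked feature by feature. AL355075.4, the lncRNA locus on chromosome 14 (20343048 to 20343685, GRCh38) that holds the RNase P RNA gene RPPH1, rose from 1.81 to 177 ± 67.5 CPM (log2 fold change 6.51 ± 0.69, adjusted p = 0.000306). MIR7977 (chromosome 3, 176515103 to 176515151) rose from 81.6 ± 14.5 to 5335 ± 3066 CPM (6.04 ± 0.73), and HP (chromosome 16, 72054592 to 72061055) from 23.3 ± 5.63 to 1412 ± 1194 CPM (5.54 ± 0.66). The U4 snRNA gene RNU4-2 fell from 487 ± 235 to 55.5 ± 18.7 CPM (log2 fold change -3.41 ± 0.57, adjusted p = 0.00192), and NFE4 from 286 ± 143 to 8.28 ± 7.11 CPM (-5.50 ± 0.73). Of 466 tRNA features, 250 rose and 5 fell (279 and 8 adjusted over the list alone), with a median log2 fold change of 2.08 against -0.04 for all features. Of 220 precursor miRNA features 130 fell and 1 rose, with a median of -3.09, and of 301 mature miRNA features 127 fell and 5 rose, with a median of -2.42. Among pseudogenes 44 rose and 4 fell (52 and 6 adjusted over the list alone). The edgeR test (Benjamini-Hochberg, adjusted p below 0.05) called 1236 of 6592 features, 586 higher and 650 lower. The set test camera called tRNA higher (adjusted p = 2.4e-38; 0.371 with an estimated correlation) and precursor miRNA lower (2.6e-19; 0.399 with an estimated correlation). Leaving out rPAL replicate 3 gave 1926 features.

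In HL60 cells the same question was asked. SCARNA6 (chromosome 2, 233288676 to 233288940) fell from 524 ± 89.9 to 0.662 ± 0.612 CPM (log2 fold change -9.79 ± 0.61, adjusted p = 4.72e-06), and the U5 snRNA gene RNU5B-1 from 1030 ± 538 to 2.33 ± 2.92 CPM (-8.99 ± 0.89). TMEM107, whose locus on chromosome 17 (8173237 to 8176399) holds the U8 snoRNA gene SNORD118, fell from 2819 ± 152 to 46.9 ± 11.3 CPM (-6.19 ± 0.27). The Y RNA gene RNY1 fell by less, from 49.9 ± 8.46 to 15.4 ± 9.45 CPM (-1.99 ± 0.51, adjusted p = 0.0124). HP rose from 20.3 ± 11.6 to 25356 ± 12503 CPM (log2 fold change 10.08 ± 0.73, adjusted p = 1.11e-05), and LINC01780 (chromosome 1, 119328176 to 119356182) from 6.02 ± 4.35 to 14997 ± 9981 CPM (11.07 ± 0.95). Of 463 tRNA features 314 rose and 17 fell (324 and 19 adjusted over the list alone), with a median of 2.16. Of 201 precursor miRNA features 179 fell and 6 rose (median -5.21, or -4.76 with features that had no rPAL count put at the floor of 3 counts over the group), of 207 miRNA features 163 fell and 11 rose (median -4.77, or -4.10 at the floor), and of 44 rRNA features 38 fell and 4 rose. Among 19 genes of the fixed C/D snoRNA list 10 fell and none rose (13 and 1 adjusted over the list alone), and of 23 H/ACA snoRNA genes 4 fell (1 adjusted over the list alone). The medians were -3.42 for the C/D list (-3.19 at the floor) and -1.17 for the H/ACA list, but -0.61 for all 367 snoRNA features. The lists match by symbol, and RNAcentral entries held 96.3% of snoRNA counts. By edgeR, 2665 of 6902 features were called, 1421 higher and 1244 lower, and camera called tRNA higher (adjusted p = 1.2e-23; 0.3 with an estimated correlation) and precursor miRNA lower (3.4e-33; 0.186 with an estimated correlation). Leaving out rPAL replicate 1 gave 4057 features, and leaving out total replicate 1, 2 or 3 gave 1744, 1741 and 1732.

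The same contrast in lEV asked whether vesicles carry the same pulled-down RNA as cells. In KG1a lEV, ATP5MG rose from 3.53 to 197 ± 208 CPM (log2 fold change 5.37 ± 1.19, adjusted p = 0.0241). HSPA8, whose locus on chromosome 11 (123057489 to 123063230) holds 3 SNORD14 genes, fell from 884 ± 615 to 40.6 ± 23.9 CPM (-4.48 ± 1.16, adjusted p = 0.027). Precursor miRNA fell, 83 of 173 features with none higher, at a median of -4.40 (-4.28 at the floor), or -4.10 relative to all features, whose median was -0.30. RNY1 (log2 fold change -3.60 ± 1.42, adjusted p = 0.112) and RNU4-2 (-3.41 ± 1.38, adjusted p = 0.121) were not called. By edgeR, 599 of 5857 features were called, 185 higher and 414 lower, and camera called precursor miRNA lower (adjusted p = 2.8e-25; 0.391 with an estimated correlation). The count rests on every library, since leaving out rPAL replicate 1, 2 or 3 gave 1030, 2116 and 1672, and leaving out total replicate 1, 2 or 3 gave 0, 266 and 242. At the 0, 1321 features had an unadjusted edgeR p under 0.05, and DESeq2, run on all libraries, called 1306. No named gene was called in every fit that left out a library.

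In HL60 lEV, Y RNA fell. RNY4P6, a Y4 pseudogene, fell from 98.97 ± 69.8 to 1.17 ± 0.592 CPM (log2 fold change -7.91 ± 1.18, adjusted p = 0.00623), and of 36 Y RNA features 26 fell and none rose (30 and 0 adjusted over the list alone; median -7.85, or -4.75 at the floor, since 17 had no rPAL count). RNU5B-1 fell from 108 ± 55.8 CPM to no count, at least 505-fold, and SNHG3, host of SNORA73A and SNORA73B, from 128 ± 79.3 to 1.61 CPM (-7.72 ± 1.85), a call that ended without total replicate 1, 2 or 3. Of 147 lncRNA features 71 rose and 21 fell, with a median of 3.53, and 27 had no count in 1 of the groups. The lncRNA share of counts nevertheless was 26.1% ± 3.08 in total and 15.3% ± 8.17 in rPAL RNA. The unnamed lncRNA ENSG00000286171.1 made 25.5% ± 3.04 and 1.25% ± 1.26 of these counts. Of 409 tRNA features 121 fell and 1 rose when adjusted over the list alone, with a median of -1.32 after TMM scaling and 0.16 without TMM, so that the class's direction depended on the scaling. By edgeR, 1006 of 3219 features were called, 396 higher and 610 lower (623 and 444 without TMM), and camera called Y RNA lower (adjusted p = 3e-09; 0.394 with an estimated correlation) and lncRNA higher (2e-09; 0.187 with an estimated correlation). Leaving out rPAL replicate 1, 2 or 3 gave 2313, 2442 and 2516 features, and leaving out total replicate 1, 2 or 3 gave 202, 207 and 251.

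For sEV the question was again the difference between rPAL and total RNA. In KG1a sEV, SCARNA6 fell from 200.1 ± 196.2 to 2.21 ± 2.77 CPM (log2 fold change -6.44 ± 1.52, adjusted p = 0.00631), HSPA8 from 4586 ± 3906 to 120 ± 137 CPM (-5.50 ± 1.16) and RNY4 from 10.8 ± 4.46 CPM to no count, at least 42.9-fold. OXCT1-AS1 rose from 0.951 to 416 ± 459 CPM (8.58 ± 1.56, adjusted p = 0.000435), and CAPZB from 7.16 to 1184 ± 1528 CPM (7.31 ± 1.37). Of 168 miRNA features 89 fell and 1 rose, with a median of -5.05 (-4.01 at the floor), or -4.63 relative to all features, and of 398 snoRNA features 29 fell and none rose (median -1.92). By edgeR, 537 of 8128 features were called, 39 higher and 498 lower, and camera called miRNA lower (adjusted p = 1.1e-26; 0.315 with an estimated correlation). Leaving out rPAL replicate 1, 2 or 3 gave 0, 0 and 278 features, and leaving out total replicate 1, 2 or 3 gave 88, 170 and 178. At the counts of 0, edgeR gave 2402 and 3064 features at an unadjusted p under 0.05, and DESeq2 on all libraries called 1122. None of the named genes was called in every such fit.

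In HL60 sEV, RNU4-2 fell from 542 ± 115 CPM to no count, at least 1755-fold (adjusted p = 0.00352), and RNU5B-1 from 158 ± 84.3 CPM to no count, at least 512-fold. LINC01780 rose from 10.6 ± 8.60 to 4551 ± 3568 CPM (log2 fold change 8.59 ± 1.27, adjusted p = 0.00561), and ZDHHC3 (chromosome 3, 44915257 to 44976185) from 8.20 ± 4.47 to 2259 ± 1766 CPM (7.96 ± 1.11). The ratio of this pair was nearly fixed over the rPAL libraries (SD 0.044 in log2), so these rises are not independent. Of 163 precursor miRNA features 116 fell and none rose (median -7.90, -7.78 relative to all features, or -5.28 at the floor), and of 12 genes of the H/ACA snoRNA list 10 fell (10 lower and 1 higher adjusted over the list alone). Of 411 tRNA features 45 fell and 1 rose (41 and 0 adjusted over the list alone), but camera did not call the class (adjusted p = 0.173). By edgeR, 681 of 3619 features were called, 91 higher and 590 lower. Leaving out rPAL replicate 1, 2 or 3 gave 264, 149 and 377 features, and leaving out total replicate 1, 2 or 3 gave 245, 283 and 213.

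The lines were then compared for the features called in each. In cells, 431 features rose in both lines against 99.6 by chance and 391 fell in both against 102.2, with 3 in opposite directions among 4686 tested in both. In lEV 80 rose in both against 9.9 by chance and 113 fell in both against 32.5, and in sEV 14 rose in both against 0.5 and 221 fell in both against 46.2. HP, LINC01780 and ZDHHC3 were called higher in all 6 sources, and 78 features fell in all 6, of which 31 were precursor miRNA, 30 unspecified ncRNA and 12 miRNA entries. These entry types may count the same reads, which was not tested. LINC01780 and ZDHHC3 kept a nearly fixed ratio over the rPAL libraries (SD 0.044 in log2), so they are not independent results. In KG1a sEV the rise came from rPAL replicate 3 alone for HP (1.56% of counts, against 0.016% and 0.019% in the other rPAL libraries and 0.012% to 0.033% in total RNA), ZDHHC3 (0.364%, against 0.003% and 0.002%, and 0.002% to 0.007% in total RNA) and LINC01780 (0.738%, against 0.0049% in both others, and 0.0038% to 0.0124% in total RNA). In KG1a lEV it came largely from replicate 3, as for HP at 1.64% against 0.031% and 0.016%. Across features, which are not independent replicates, the log2 fold changes of the lines had r = 0.741 in cells, 0.648 in lEV and 0.634 in sEV. The lines share no control library.

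**Figure D2:**
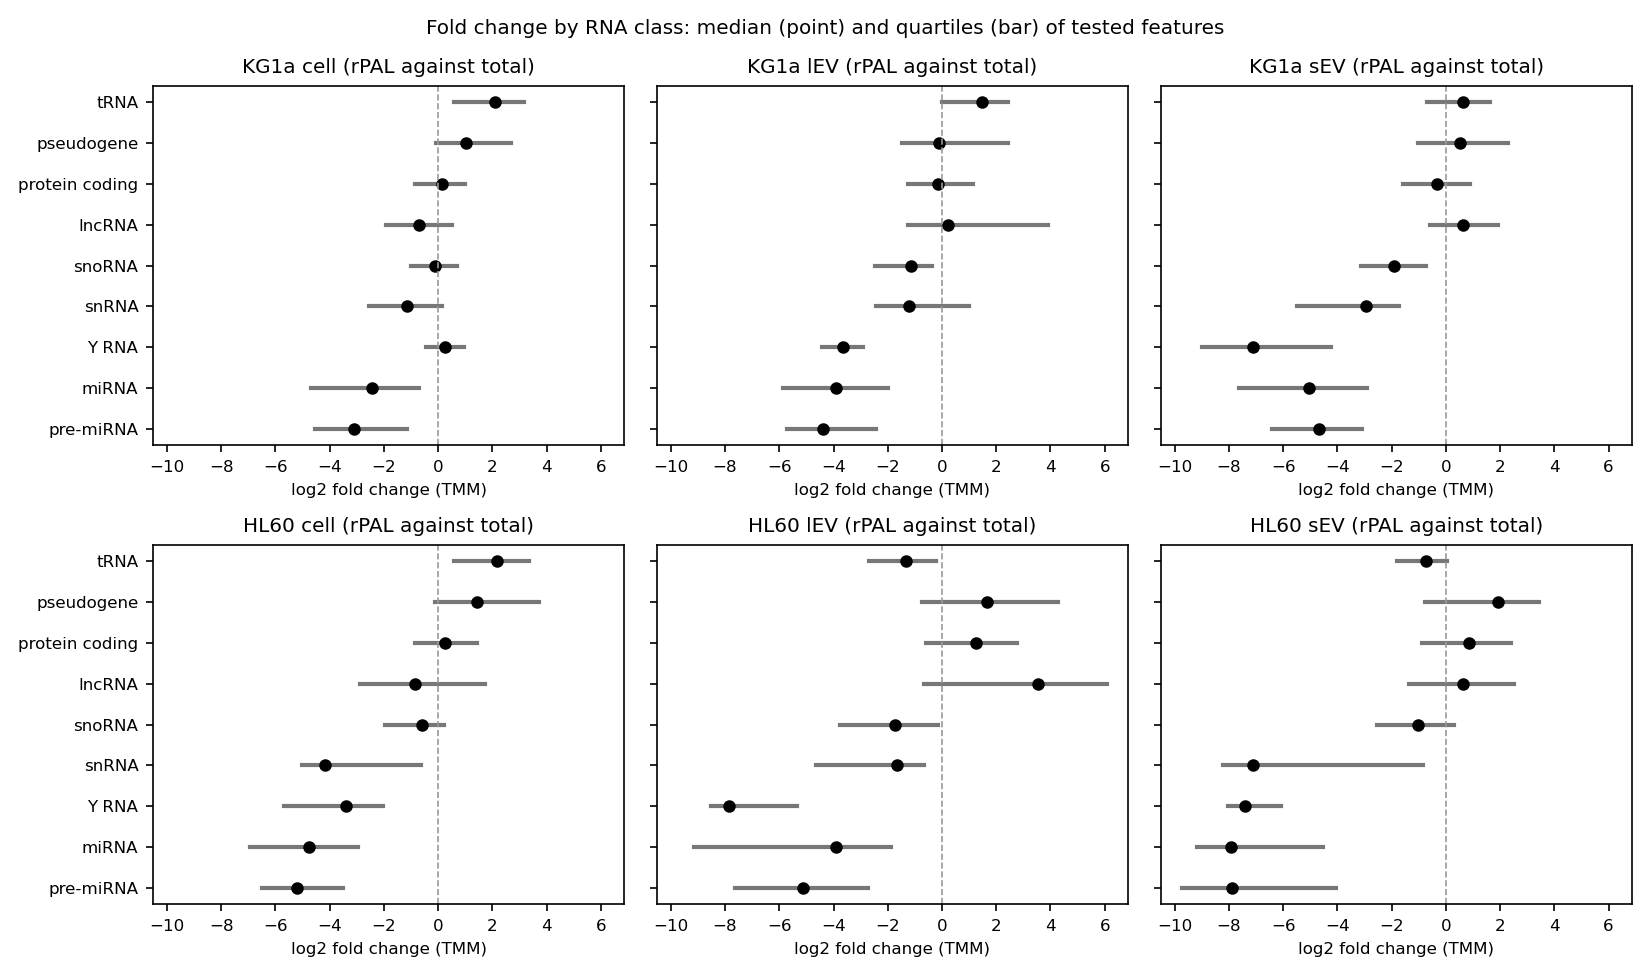
Median (point) and quartiles (bar) of the log2 fold change of rPAL over total RNA (x axis) for the tested features of 9 RNA classes, with 1 panel for each line and source. Precursor miRNA lay between -3.09 in KG1a cells and -7.90 in HL60 sEV (-5.28 with features that had no rPAL count put at the floor), and tRNA was at 2.16 in HL60 cells and -1.32 in HL60 lEV, where it was 0.16 without TMM.

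Total RNA was compared between lEV and cells to ask which small RNAs the large vesicles carry. In KG1a, RNY1 (chromosome 7, 148987136 to 148987248) rose from 50.3 ± 13.8 to 308 ± 53.1 CPM (log2 fold change 2.49 ± 0.36, adjusted p = 5.14e-05) and RNY4 from 1.38 ± 0.468 to 33.3 ± 10.5 CPM (4.44 ± 0.43). FP671120.4, annotated as a lncRNA locus on chromosome 21 (8254592 to 8255514), rose from 83.9 ± 25.8 to 1424 ± 34.7 CPM (adjusted p = 9.21e-07), and RPL13A from 4.28 ± 0.86 to 18.05 ± 3.42 CPM (1.95 ± 0.34). Over all libraries FP671120.4 had 569551 counts, close to FP236383.3 (570878), FP671120.3 (571509) and FP236383.2 (574475) on the same chromosome. Its rise therefore cannot be placed at this locus alone. ZMYM2 fell from 639 ± 352 to 12.6 ± 1.88 CPM (log2 fold change -5.78 ± 0.56, adjusted p = 2.13e-06) and ZIM2 from 105 ± 73.5 CPM to no count, at least 1164-fold. Of 18 Y RNA features 17 rose and none fell (17 and 0 adjusted over the list alone; median 4.10), 6 of 8 7SL features rose (median 3.86), and of 71 ribosomal protein mRNAs 48 rose and 7 fell (50 and 7 adjusted over the list alone; median 1.30). Of 714 lncRNA features 593 fell and 44 rose (median -3.20, or -3.18 at the floor). The lncRNA share of counts nevertheless was 3.79% ± 0.727 in cells and 14.7% ± 9.55 in lEV, most of it from the unnamed lncRNA ENSG00000286171.1 (2.77% ± 0.892 and 13.2% ± 9.54). Of 321 miRNA features 233 fell and 6 rose (median -1.58). By edgeR, 4067 of 7780 features were called, 1851 higher and 2216 lower. Camera called Y RNA higher (adjusted p = 3.2e-11; 0.264 with an estimated correlation), ribosomal protein mRNAs higher (4e-08; 0.38 with an estimated correlation) and lncRNA lower (2.2e-32), and the lncRNA call held with an estimated correlation (adjusted p = 0.0116).

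In HL60, Y RNA also rose in lEV over cells. RNY3 rose from 11.5 ± 1.00 to 54.2 ± 6.67 CPM (log2 fold change 3.14 ± 0.58, adjusted p = 0.0021), RNY4 from 3.23 ± 0.461 to 38.9 ± 19.4 CPM (4.57 ± 0.72) and RNY1 from 49.9 ± 8.46 to 220.01 ± 140.8 CPM (3.13 ± 0.70), although RNY1 was no longer called without cell replicate 1 or 3. ZMYM2 fell from 1117 ± 354 to 41.1 ± 13.9 CPM (-3.93 ± 0.58), and MPO, the myeloperoxidase mRNA, rose from 2.49 ± 0.94 to 6.02 ± 1.39 CPM (2.15 ± 0.48, adjusted p = 0.00593). Of 44 Y RNA features 43 rose and none fell (43 and 0 adjusted over the list alone), at a median of 4.44, or 4.28 relative to all features. Of 462 lncRNA features 290 fell and 15 rose (median -2.35), of 211 miRNA features 95 fell and 2 rose (median -1.46), and of 73 ribosomal protein mRNAs 27 rose and 4 fell (27 and 5 adjusted over the list alone). By edgeR, 1784 of 6527 features were called, 790 higher and 994 lower, or 44.3% higher (10.9% without TMM, with 1588 lower), and camera called Y RNA higher (adjusted p = 1.8e-21; 0.33 with an estimated correlation) and lncRNA lower (6.1e-29), which held with an estimated correlation (adjusted p = 0.0343). Leaving out cell replicate 1 or 3 gave 1025 and 1059 features. Of 5263 features tested in both lines, 492 rose in both against 167 by chance and 730 fell in both against 212.5.

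Small vesicles were compared with cells in the same way. In KG1a sEV the mitochondrial tRNA gene MT-TN (mitochondrial genome, 5657 to 5729) fell from 247 ± 125.6 to 8.34 ± 4.97 CPM (log2 fold change -6.07 ± 0.67, adjusted p = 0.000133), and all 13 mitochondrial mRNAs fell (13 adjusted over the list alone), MT-CYB by the most among them at -4.13 ± 0.43 and with a median of -3.48. RNY4 rose from 1.38 to 10.8 ± 4.46 CPM (1.95 ± 0.49, adjusted p = 0.00719), while RNY1 was not called (-0.41 ± 0.60, adjusted p = 0.603). KCNQ1OT1 rose from 1.19 to 8.70 ± 2.46 CPM (1.81 ± 0.40), and NFE4 fell from 286 ± 143 to 9.06 ± 3.50 CPM (-6.00 ± 0.69). Of 319 miRNA features 241 fell and 11 rose (median -2.17, or -2.39 relative to all features), and of 442 snoRNA features 200 rose and 68 fell (median 1.26). Of 54 histone mRNAs 13 fell and none rose (10 and 0 adjusted over the list alone), with a median of -0.47 that was 0.56 without TMM. By edgeR, 3933 of 8725 features were called, 2009 higher and 1924 lower (4362 and 1011 without TMM). Camera called mitochondrial mRNAs lower (adjusted p = 7.6e-09; 0.365 with an estimated correlation) and protein-coding features higher (6.7e-14), and the protein-coding call held with an estimated correlation (adjusted p = 0.0245).

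In HL60 sEV against HL60 cells, MT-TN fell from 376 ± 160 to 2.15 ± 0.723 CPM (log2 fold change -7.74 ± 0.57, adjusted p = 0.00068) and MT-ND1 from 489 ± 74.4 to 31.7 ± 11.4 CPM (-4.22 ± 0.38, adjusted p = 0.00068). Of 13 mitochondrial mRNAs 11 fell (13 adjusted over the list alone; median -2.32, or -2.48 relative to all features), and of 21 mitochondrial tRNA features 19 fell (median -5.12). RNY4 rose from 3.23 to 15.8 ± 3.40 CPM (2.02 ± 0.48, adjusted p = 0.0154), a call that ended without cell replicate 1, 2 or 3, and of 23 Y RNA features 12 rose and none fell (13 and 0 adjusted over the list alone; median 2.02). Of 50 histone mRNAs 12 fell (19 adjusted over the list alone; median -1.11). By edgeR, 2018 of 7555 features were called, 1048 higher and 970 lower (1397 and 781 without TMM), and camera called mitochondrial tRNA lower (adjusted p = 1.2e-14; 0.236 with an estimated correlation). Leaving out cell replicate 1, 2 or 3 gave 552, 527 and 631 features, and leaving out sEV replicate 3 gave 3981. Among 6082 features tested in both lines, 520 rose in both against 197.1 by chance and 727 fell in both against 188.7.

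**Figure D3:**
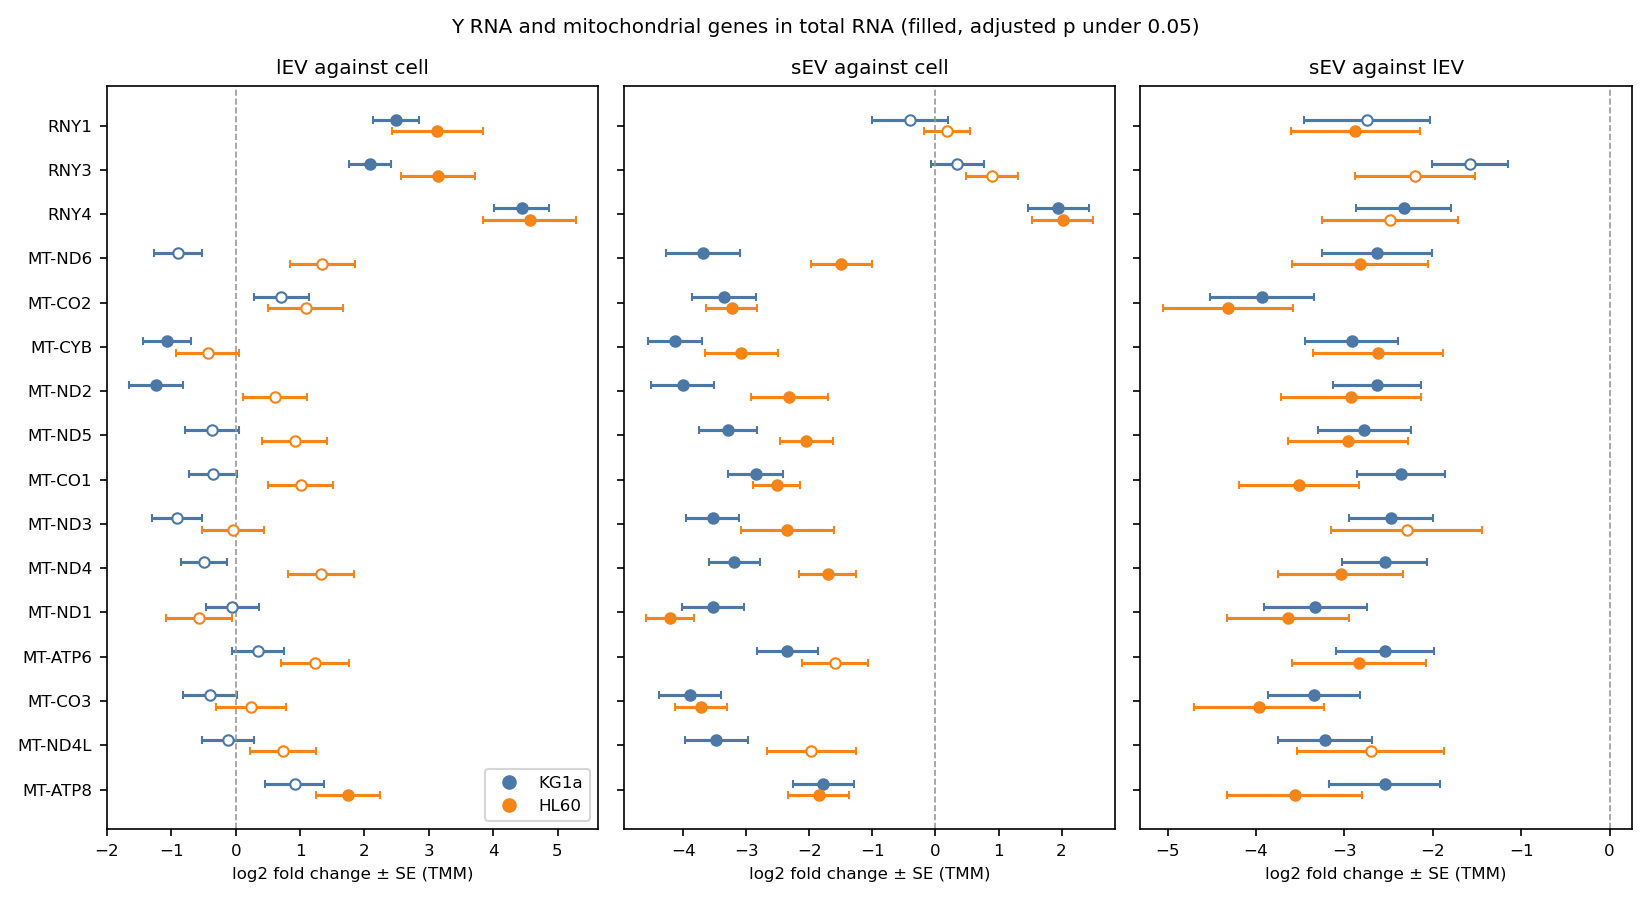
Log2 fold change ± SE (x axis) of RNY1, RNY3, RNY4 and 13 mitochondrial mRNAs in total RNA of KG1a and HL60, for lEV over cells, sEV over cells and sEV over lEV, with filled points at an adjusted p under 0.05. RNY4 was 4.44 in KG1a and 4.57 in HL60 for lEV over cells, and MT-CO2 was -3.93 in KG1a and -4.32 in HL60 for sEV over lEV.

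The vesicle kinds were then set against each other. In KG1a, MT-CO2 fell from 317 ± 130 in lEV to 37.1 ± 11.2 CPM in sEV (log2 fold change -3.93 ± 0.59, adjusted p = 0.0336), and all 13 mitochondrial mRNAs fell (13 adjusted over the list alone), at a median of -2.63, or -2.76 relative to all features. RNY4 fell (-2.33 ± 0.54, adjusted p = 0.0414), and of 17 Y RNA features 6 fell (13 adjusted over the list alone; median -2.20). Of 434 tRNA features 73 fell and 3 rose (242 and 26 adjusted over the list alone; median -1.51), and of 411 snoRNA features 24 rose and 4 fell (median 1.33). Genes of the H/ACA snoRNA list rose, 7 of 22 (16 adjusted over the list alone), and 2 of 14 C/D snoRNA genes rose (3 adjusted over the list alone). By edgeR, 408 of 7682 features were called, of which 262 or 64.2% were higher (94.5% of 1500 without TMM), and a fit with the replicate number as a block called 1107. Camera called mitochondrial mRNAs lower (adjusted p = 2.3e-15; 0.3 with an estimated correlation) and tRNA lower (4.4e-35; 0.186 with an estimated correlation). Leaving out lEV replicate 1, 2 or 3 gave 0 features, with 1536, 1519 and 1844 at an unadjusted edgeR p under 0.05, and DESeq2 on all libraries called 771. Leaving out sEV replicate 1 gave 634, and no named gene was called in every such fit.

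In HL60, MT-CO2 fell from 225 ± 98.7 in lEV to 25.5 ± 7.14 CPM in sEV (log2 fold change -4.32 ± 0.74, adjusted p = 0.0148) and MT-CO1 from 145 ± 70.4 to 25.6 ± 7.87 CPM (-3.51 ± 0.68). Of 13 mitochondrial mRNAs 11 fell (13 adjusted over the list alone; median -2.96). RNY1 fell (-2.87 ± 0.73, adjusted p = 0.0333), RNY4 was not called (-2.49 ± 0.77, adjusted p = 0.0707), and of 49 Y RNA features 12 fell and none rose (37 adjusted over the list alone; median -2.43). Of 262 lncRNA features 64 rose and 4 fell (median 1.07), although the lncRNA share of counts was 26.1% ± 3.08 in lEV and 15.6% ± 2.43 in sEV. By edgeR, 419 of 5813 features were called, 317 higher and 102 lower (1063 and 36 without TMM), and camera called mitochondrial mRNAs lower (adjusted p = 6.9e-15; 0.295 with an estimated correlation). Leaving out lEV replicate 1, 2 or 3 gave 0 features, with 1568, 1816 and 1449 at an unadjusted edgeR p under 0.05, and DESeq2 on all libraries called 958. Leaving out sEV replicate 1, 2 or 3 gave 207, 265 and 1589, and no named gene was called in every such fit. Among 4905 features tested in both lines, 92 rose in both against 7.7 by chance and 52 fell in both against 2.3.

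Whether the enrichment differed between vesicles and cells was tested as the difference of the rPAL over total changes. In HL60 lEV, GAS5, with only 2 counts in lEV rPAL, was enriched less than in cells (difference -8.48 ± 1.07 in log2, adjusted p = 0.000282). Of 479 tRNA features 219 had a lower enrichment in HL60 lEV than in cells and none a higher one (297 and 0 adjusted over the list alone), with a median difference of -3.10, or -2.31 relative to all features, whose median was -0.79. In HL60 sEV, RNU4-2 (adjusted p = 0.00156, without a size since sEV rPAL had no count) and RNY1 (-6.60 ± 1.31, adjusted p = 0.00652, with only 2 counts in sEV rPAL and not called without cell total replicate 1 or 3) were lost more than in cells, and 268 of 479 tRNA features were lower (345 lower and 1 higher adjusted over the list alone; median -3.85, or -2.33 relative to all features; -3.70 over those with a count in all 4 groups). By edgeR, 1075 of 8458 features for HL60 lEV were called, 113 higher and 962 lower (118 and 367 without TMM, 132 and 318 with RLE, 537 and 776 with DESeq2). For HL60 sEV it called 1073 of 8107, 38 higher and 1035 lower (39 and 100 with RLE, 328 and 554 with DESeq2). Camera called tRNA lower in HL60 lEV (adjusted p = 1.5e-26; 0.251 with an estimated correlation) and in HL60 sEV (2.2e-32; 0.186 with an estimated correlation), and lncRNA higher against other features in HL60 lEV (1.8e-06), with 29 higher, 40 lower and a median of 0.06 (0.72 without the 321 features with no count in a group), which held with an estimated correlation (adjusted p = 0.0495). For HL60 lEV, leaving out cell total replicate 2 or 3 gave 169 and 185 features and replicate 1 a count between these. Leaving out lEV total replicate 1, 2 or 3 gave 443, 596 and 377, and lEV rPAL replicate 2 gave 2039. For HL60 sEV, leaving out cell rPAL replicate 1, 2 or 3 gave 479, 632 and 456, cell total replicate 1, 2 or 3 gave 183, 184 and 185, sEV total replicate 1, 2 or 3 gave 162, 591 and 548, and sEV rPAL replicate 2 gave 616.

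In KG1a, edgeR called few such differences and DESeq2 more. OXCT1-AS1 was enriched more in sEV than in cells (difference 10.47 ± 1.68 in log2, adjusted p = 0.00153) and was 1 of 8 features called by edgeR of 13700, 5 higher and 3 lower (9 and 36 without TMM, 15 and 3 with RLE), while DESeq2 called 378. At a simulated 16-fold change edgeR called 4% of features in KG1a sEV and 2% in KG1a lEV. DESeq2 called 18% and 24% there, but also 10 and 21 unchanged features, so its counts may hold false calls. For KG1a lEV the edgeR test called 0 of 10442 features, with 1498 at an unadjusted p under 0.05, and DESeq2 called 403. Y RNA had a median difference of -3.03 in KG1a lEV, or -2.52 relative to all features. None of its 20 features was called (adjusted p of camera 1e-08; 0.236 with an estimated correlation). In KG1a sEV none of 10 was called (4 lower adjusted over the list alone), with a median of -4.13 over the 5 that had a count in all 4 groups. Without lEV rPAL replicate 2, 43 features were called for KG1a lEV. For KG1a sEV, leaving out cell rPAL replicate 1, 2, 3 or 4 gave 4, 3, 2 and 16 features, cell total replicate 1, 2 or 4 gave 3, 2 and 2, sEV rPAL replicate 1, 2 or 3 gave 3, 14 and 37, and sEV total replicate 1, 2 or 3 gave 3, 4 and 2. The lines were not tested against each other for this difference in vesicles.

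The total RNA of HL60 cells was compared with that of KG1a cells to ask how the lines themselves differ. CD34, a marker of primitive blood cells, fell from 2.95 ± 1.47 CPM in KG1a to 0.07 in HL60 (log2 fold change -5.13 ± 0.63, adjusted p = 2.99e-06), and all 4 tested genes of the stem cell list fell (4 adjusted over the list alone). MPO rose to 2.49 ± 0.94 CPM in HL60 (6.44 ± 0.66, adjusted p = 2.83e-07), the only tested gene of the neutrophil granule list (1 adjusted over the list alone). TMEM107 rose from 7.67 ± 1.85 to 2819 ± 152 CPM (8.62 ± 0.30, adjusted p = 5.03e-14) and SCARNA6 from 28.1 ± 14.3 to 524 ± 89.9 CPM (4.31 ± 0.41). CDK6 (chromosome 7, 92604921 to 92836594) fell from 143.6 ± 22.9 to 1.74 ± 0.356 CPM (-6.28 ± 0.37), and its locus holds the U6 snRNA pseudogene RNU6-10P. NEAT1 fell from 22.6 ± 4.54 to 8.09 ± 1.85 CPM (-1.41 ± 0.32), as did 2 of 3 tested genes of the nuclear lncRNA list (2 adjusted over the list alone), and MIR29A, the only tested gene of the myeloid miRNA list, rose (adjusted p = 0.0011; 1 adjusted over the list alone). All 3 tested let-7 genes fell (3 adjusted over the list alone; median -2.38), of 359 miRNA features 210 fell and 44 rose (median -1.37), and of 74 ribosomal protein mRNAs 38 rose and 2 fell (39 and 2 adjusted over the list alone; median 0.79). Of 19 C/D snoRNA genes 11 rose and none fell (11 and 0 adjusted over the list alone; median 1.04). By edgeR, 3456 of 8655 features were called, 1593 higher and 1863 lower, and camera called miRNA lower (adjusted p = 3e-11; 0.236 with an estimated correlation) and ribosomal protein mRNAs higher (4.5e-06; 0.59 with an estimated correlation).

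Enrichment in cells was last compared between the lines. TMEM107 (difference -6.44 ± 0.92 in log2, adjusted p = 0.00184), SCARNA6 (-5.92 ± 0.91) and RNU5B-1 (-6.56 ± 1.07) were lost further in HL60 than in KG1a cells, and LINC01780 (4.88 ± 1.00, adjusted p = 0.0211) and ZDHHC3 (5.29 ± 0.97) were enriched further. Neither of the last pair was called without HL60 rPAL replicate 1 or HL60 total replicate 1 or 2, nor was LINC01780 without HL60 rPAL replicate 3 or KG1a total replicate 4. Since LINC01780 and ZDHHC3 kept a nearly fixed ratio over the rPAL libraries (SD 0.044 in log2), their differences are not independent. Of 46 rRNA features 10 were lower and none higher (34 and 0 adjusted over the list alone), with a median of -2.59, or -2.23 relative to all features, whose median was -0.36. Of 48 snRNA features 12 were lower (25 adjusted over the list alone; median -3.15, or -2.52 over those with a count in all 4 groups), while the median of 494 tRNA features was 0.01. By edgeR, 211 of 11632 features were called, 74 higher and 137 lower, and camera called rRNA lower (adjusted p = 7e-15; 0.207 with an estimated correlation) and snRNA lower (1.8e-14; 0.173 with an estimated correlation). Leaving out HL60 rPAL replicate 1, 2 or 3 gave 34, 60 and 36 features, HL60 total replicate 1, 2 or 3 gave 14, 20 and 36, KG1a rPAL replicate 1 or 4 gave 432 and 595, and KG1a total replicate 1, 2, 3 or 4 gave 102, 45, 43 and 49.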

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

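The tests of the recurrent features, of the libraries that stand apart and of other splits of the same libraries were chosen only after those results were seen. The tests of rRNA taking tRNA counts, of swapped line labels and of lower depth were chosen before.

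A recurrent set of 57 features was higher in rPAL than in total RNA in at least 4 of 6 sources and lower in none, and HP, LINC01780, ZDHHC3 and AL391684.1 were called higher in all 6, although in KG1a sEV the rises of HP, LINC01780 and ZDHHC3 came from rPAL replicate 3 alone and that of AL391684.1 largely so (0.0736% against 0.0012% and 0.0027%). The set held 59.4% ± 0.642 of rPAL counts in HL60 lEV and 10.3% ± 2.87 in KG1a cells, but it was picked for being high there, and in vesicles the pair of unnamed rRNA entries made most of it (72.1% in HL60 lEV). Across 19 rPAL libraries, within groups, the set took a larger share where a library held fewer other features at equal depth (Spearman rho -0.719, permutation p = 0.00012; Pearson r -0.674, permutation p = 5e-05; r -0.544 without the 2 farthest libraries), which is consistent with a background that fills poorer libraries. A single source with fixed proportions is argued against for the set as a whole, whose members varied against the rest by a median SD of 2.02 in log2. For the 4 features higher in all 6 sources the median SD was 0.483, only just inside the bound set for that test. The SD was 0.044 between ZDHHC3 and LINC01780, at a mean log2 ratio of -0.972, while their shares varied by SDs of 2.84 and 2.87. Whether both count the same reads was not tested, so the median rests in part on a pair that is not independent. The SD was 1.07 between either and AL391684.1, so fixed proportions are not shown for all 4. Enrichment of sialylated RNA stays open, since no pull-down without oxidation was among the samples.

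The share of tRNA was higher in rPAL than in total RNA of cells and lower in HL60 vesicles. That a library that stood apart made the difference is argued against in HL60 sEV, where it was -26.3 points without that library, but was not tested in HL60 lEV, where none stood apart. Whether rRNA took the counts cannot be told apart, since with rRNA left out the difference was -18.9 points in HL60 lEV, where libraries overlapped, and -26.2 points in HL60 sEV, where they did not, while over all 6 sources the mean difference went from 6.02 to 15.6 points. A difference between cells and vesicles in glycosylated tRNA, and the serum-free culture of vesicle donors, were not tested.

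Replicate 3 of the KG1a lEV and of the KG1a sEV rPAL libraries stood apart from replicates 1 and 2. Lower depth alone is argued against, if narrowly, since thinned to the depth of replicate 3 the others still held at least 1.57 times as many features. HL60 libraries under a KG1a label cannot be told apart, because the line scores of replicate 3 (2.34 in lEV, 1.17 in sEV) lay within the range of HL60 vesicle rPAL libraries (0.811 to 5.15), and the other KG1a libraries (1.23 to 5.42) spanned nearly the same range. LINC01766 made 7.21% (lEV) and 11.5% (sEV) of counts in replicate 3, within the 1.77% to 16.1% of HL60 vesicle rPAL libraries. The other KG1a vesicle rPAL libraries had 0.198% to 0.442%. It belongs to the recurrent set, which took more of poorer libraries, so its share does not decide the label either. No biological explanation was tested.

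Mitochondrial tRNA made 0.875% of counts in KG1a cell rPAL replicate 2, against 0.365% to 0.397% in the other 3 libraries. AC008735.5 had 0.084 CPM in KG1a cell total replicate 4, a single count, and 0 in the other 3. Such distant values occur by chance in about 1 in 20 groups, and 2 of 104 tested were found. The enrichment differed between sEV and cells for 8 features in KG1a and for 1073 in HL60, between lEV and cells for 1075 features in HL60, and between HL60 and KG1a cells for 211 features.

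The counts were also set against other splits of the same libraries. In KG1a cell enrichment 1 of 35 splits, the real one, reached 1236 features and the highest other gave 0. The same held for KG1a lEV against cells (1 of 35, 4067 against 5), KG1a sEV against cells (1 of 35, 3933 against 2) and HL60 against KG1a cells (1 of 35, 3456 against 1). This is the smallest share that 35 splits allow, without adjustment for the number of comparisons, so it argues against chance but does not exclude it. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real split alone, 1 of 10, gave the highest count, with 599 in KG1a lEV, 2665 in HL60 cell, 1006 in HL60 lEV and 681 in HL60 sEV enrichment against 0 in any other split, and 537 in KG1a sEV enrichment against 4. The same holds for sEV against lEV (408 in KG1a without a block, 419 in HL60) and for HL60 vesicles against cells (1784 for lEV, 2018 for sEV), with 0 in any other split. In KG1a, where replicate numbers pair these vesicle libraries, the blocked fit called 1107, against 0 in each of the other 3 splits that part every pair, a comparison added after the counts were seen. These 4 splits are again too few. For the differences in enrichment 100 splits were drawn. At least as many features were called in 2 of 100 for HL60 lEV (1075, highest other 2213), HL60 sEV (1073, highest other 2431) and the lines (211, highest other 906). These splits exchange source or line labels within each RNA kind, so some of them carry the difference between sources or lines. Their counts therefore cannot tell a difference in enrichment from chance. In KG1a 12 of 100 splits reached the 8 of sEV (highest other 2686), so chance is not excluded there either. For KG1a lEV edgeR called 0 (1498 features at an unadjusted p under 0.05, 403 by DESeq2), which any split reaches (100 of 100; highest other 1832), so the splits say nothing about it. In HL60 lEV, HL60 sEV and the lines, the split with the highest count keeps the real rPAL groups and permutes only the total libraries, so it carries the difference between sources or lines itself, a structure of the samples. In KG1a it sets 3 cell rPAL libraries against the vesicle ones and 1 cell library.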

How the results depend on the processing

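Of the named-gene values, 2617 kept their direction and call, 416 were no longer called and 0 reversed, and 280 of these 416 losses came from leaving out a library. Collapsing near-identical features, the class shares in subsets and the value without a library that stands apart were chosen after seeing the data. The cause was not tested for any change below, except that all 12 groups in one fit share the spread of all libraries. A simulated 16-fold change was called in the vesicle enrichments for 0% to 7.5% of features by edgeR and 34% to 64% by DESeq2, and in the differences in enrichment for 0% to 20% and 10% to 46%, and how much of this is due to depth, spread or tool was not separated. DESeq2 also called unchanged simulated features. In HL60 sEV enrichment it called 28 of these beside 19 of 50 changed 16-fold, and in KG1a lEV enrichment 17 beside 32 of 50. Its larger counts below may therefore hold false calls.

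With DESeq2 the counts were 1306 in KG1a lEV, 1122 in KG1a sEV and 1175 in HL60 sEV enrichment, 771 and 958 for sEV against lEV in KG1a and HL60, and, for differences in enrichment, 403 in KG1a lEV, 378 in KG1a sEV and 705 between lines. Without TMM, sEV against lEV gave 1500 in KG1a and 1099 in HL60, and the differences gave 26 in KG1a lEV, 45 in KG1a sEV, 485 in HL60 lEV and 122 between lines. With RLE scaling the differences gave 10 in KG1a lEV, 18 in KG1a sEV, 450 in HL60 lEV and 139 in HL60 sEV. With no filter the enrichments gave 1 in KG1a lEV, 26 in KG1a sEV, 309 in HL60 lEV and 226 in HL60 sEV, total RNA gave 6107 for KG1a lEV against cells, 1130 for KG1a sEV against lEV, 3903 for HL60 sEV against cells and 1824 for HL60 sEV against lEV, and the differences gave 20 in KG1a sEV, 384 in HL60 lEV and 541 in HL60 sEV. With 10 counts in every library of a group the enrichments gave 1019 in KG1a lEV, 840 in KG1a sEV and 1149 in HL60 sEV, and the difference 22 in KG1a lEV. With all 12 groups in one fit the enrichments gave 1162 in HL60 cells, 3757 in HL60 lEV and 3108 in HL60 sEV, and total RNA gave 88 and 627 for KG1a lEV and sEV against cells, 44 for KG1a sEV against lEV, 36 and 587 for HL60 lEV and sEV against cells and 165 between lines. With near-identical features collapsed the differences gave 636 in HL60 sEV and, to 2 digits, 1.3e+02 between lines.

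With the replicate block the enrichments gave 233 in KG1a lEV, 182 in KG1a sEV, 641 in HL60 lEV and 322 in HL60 sEV, KG1a sEV against lEV gave 1107, and the differences gave 4 in KG1a sEV, 449 in HL60 lEV, 549 in HL60 sEV and 57 between lines; no other count moved by over 1.5 times. Of the class tests, 4 were called with an estimated correlation against 210. Between 14 and 17 class shares were called in the alternatives, against 16, and the tRNA share was called without rRNA in the total (15.6 points) and in cells only (46.97 points). Shares reversed for lncRNA without the most abundant feature (9.45 points), for rRNA in cells only (-0.719 points) and for mitochondrial tRNA in vesicles only (-0.00575 points).

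Leaving out 1 library gave, for the enrichments, 915 to 1926 in KG1a cells, 0 to 2116 in KG1a lEV, 0 to 278 in KG1a sEV, 1732 to 4057 in HL60 cells, 202 to 2516 in HL60 lEV and 149 to 377 in HL60 sEV. For total RNA it gave 3109 to 4524 and 2818 to 4745 for KG1a lEV and sEV against cells, 0 to 634 for KG1a sEV against lEV, 1025 to 2593 and 527 to 3981 for HL60 lEV and sEV against cells, 0 to 1589 for HL60 sEV against lEV and 2839 to 3400 between lines. For the differences it gave 0 to 43 in KG1a lEV, 2 to 37 in KG1a sEV, 169 to 2039 in HL60 lEV, 162 to 1318 in HL60 sEV and 14 to 595 between lines. The counts of 0 are by edgeR, with at least 1177 features at an unadjusted p under 0.05. Leaving out a replicate number left 14 to 16 class shares called.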

Other observations

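Single features took large shares of some libraries, and these were picked out after the values were seen. PCNA made 0.061%, 40.1% and 1.44% of counts in the HL60 sEV rPAL libraries and 3.29% in 1 HL60 sEV total library, and its share was at most 0.008% in every HL60 lEV rPAL library. LINC01766 made 11.9% ± 6.65 of counts in HL60 cell rPAL RNA against 0.0147% ± 0.0074 in HL60 cell total RNA. It made 1.77% to 16.1% in HL60 vesicle rPAL libraries. In KG1a vesicle rPAL libraries it made 7.21% (lEV) and 11.5% (sEV) in replicate 3, but 0.198% to 0.442% in the others. An unnamed lncRNA, ENSG00000286171.1, made 27.3% ± 4.46 of counts in HL60 cell total RNA and 2.77% ± 0.892 in KG1a cell total RNA, but 25.5% ± 3.04 in HL60 lEV and 13.2% ± 9.54 in KG1a lEV total RNA, and 13.2% ± 3.44 in HL60 sEV and 7.27% ± 5.01 in KG1a sEV total RNA.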
